A study of Mus musculus with 22 samples.

How the data were processed

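Lamin A/C (antibodies 3A6 and E1), BRG1, CHD4 and Lap2alpha (antibody 1H11) were mapped by ChIP-seq in mouse dermal fibroblasts, wildtype or without Lap2alpha. Per the labels' protocols, cells were crosslinked with both DSG and formaldehyde and chromatin was sheared in a bath sonicator, for 16 or 20 cycles as the sample titles give. Groups were taken from the sample titles, with 1 library per genotype, antibody and sonication length. Of 22 samples, 18 had a region list used here; input libraries were not analysed here.

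The authors deposited each library as a list of intervals with 3 columns, the chromosome, start and end in base pairs. The deposited lists carry no height, fold or significance, so no threshold on peak strength could be applied and all listed intervals count alike. Coordinates are on GRCm38, per the submitters' processing notes, which also list SAMtools, deepTools, MACS2 2.1.4, bedtools and HOMER 4.11.1. The roles of these tools, the calling threshold, the control used and any pooling of libraries are not given in the sources used here. A library with more reads or a looser threshold gives a longer list, so numbers of regions are not amounts of protein.

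In 7 lists some intervals overlapped each other, mostly nested around a shared centre and with widths limited to a common maximum in several of them, while 11 lists held no overlapping intervals. Lists of these 2 forms were paired for 3A6, BRG1 and CHD4 at 20 cycles. Overlapping intervals of a list were therefore merged into regions, a step chosen after seeing the lists, and values for the intervals as listed were computed as an alternative. Intervals of width 0 (1 to 1201 per list) and on the mitochondrial genome (5 in KO 3A6 at 20 cycles, 1 in WT Lap2alpha at 16 cycles) were left out.

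Genes were the 21887 protein-coding genes on assembled chromosomes of the RefSeq table for GRCm38. It gives no strand, so the planned promoter windows were replaced by windows of 1 kb to each side of both gene ends, and gene-end shares include 3' ends. Gene density was the number of protein-coding genes in each of 2732 bins of 1 Mb, and gene-rich and gene-poor bins were the 683 bins with the most (11 or more) and fewest (2 or fewer) genes. Genome sequence was not used here, so the planned GC content and motif counts were not run.

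Overlap meant at least 1 bp. It was set against 100 random placements of the query regions on the same chromosomes, uniform over the span between the outermost regions, which includes assembly gaps and repeats; a shift of 10 kb was computed as a local control. For each matched pair the log2 ratio of region numbers and covered lengths, or the difference of shares in percentage points, KO minus WT, was taken and given as mean ± SD over pairs with the number of pairs in each direction. With 1 library per group no test was run and no p-value is given. Shares have 95% Wilson intervals where stated. Neighbouring regions are not independent, so these intervals are narrower than the real error.

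For each gene the percent of its body covered by regions and the presence of a gene-end region were computed per library. For 18 gene lists the share of members with a gene-end region and the mean body coverage were compared with 10000 random lists matched on deciles of gene length, as a description of these libraries; tissue-specific families lie in clusters, so their members are not independent. Prefix rules defined the HOX, olfactory, vomeronasal, histone and zinc finger lists, and all members of the other lists were found.

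Named genes followed a fixed rule. Lamin A/C gene bodies of 5 kb or more were named if they differed one way in all 4 pairs, the 10 largest mean differences each way. Gene ends were named if present in all lists of one genotype and none of the other, up to 10 ranked by the smallest width, over the libraries, of the widest region. Lap2alpha gene ends present at both lengths were ranked likewise, and up to 4 members of each list that differed one way in all pairs of an antibody were eligible. Olfactory, vomeronasal and predicted genes were counted but not named.

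The comparisons, gene lists, naming rule and a first set of alternative settings were fixed before the data were examined. Alternatives covered wider merging, a minimum width, equal numbers of the widest regions (in place of a score), autosomes only, each sonication length or antibody alone, other gene-end and bin sizes, and a 50% overlap rule. Chosen after seeing the data were the intervals as listed, pairs of lists of the same form, the omission of the 3A6 pair at 16 cycles, 200 bp windows at region centres, equal chromosome weights, the gene-rich shares of BRG1 and CHD4, and the BRG1 sites shared between libraries. Interval functions were tested on simulated intervals, where 15 quantities were recovered within 0.334%. The matched lists were tested on simulated values for the 21887 genes, where 100 random lists had a median percentile of 49.6 and 100 shifted lists had percentiles of 100. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.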

Results

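Chromatin immunoprecipitation with sequencing (ChIP-seq), which maps where a protein sits on the genome, was analysed for mouse dermal fibroblasts, the matrix-producing cells of the skin. The cells were wildtype (WT) or lacked Lap2alpha (KO), a nucleoplasmic LAP2 protein that binds A-type lamins in the nuclear interior. Lamin A/C, the A-type lamins, was precipitated with 2 antibodies, 3A6 and E1. BRG1, the ATPase of SWI/SNF (BAF) chromatin remodellers, and CHD4, the ATPase of the NuRD complex, were precipitated in both genotypes. Lap2alpha itself was mapped in WT cells with antibody 1H11; Lap2alpha ChIP in KO cells was not analysed here. Chromatin was sonicated for 16 or 20 cycles, and each combination of genotype, antibody and sonication length was 1 library, giving 18 region lists.

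The lists held between 7283 regions (KO CHD4, 20 cycles) and 233769 regions (KO lamin A/C, E1, 20 cycles). WT and KO lists of one antibody and one sonication length formed 8 matched pairs, 4 for lamin A/C and 2 each for BRG1 and CHD4. No group had a replicate, and the matched pairs differ in antibody or sonication rather than in cells, so no test was run. Means ± SD over libraries or pairs show how far values spread over antibodies and sonication lengths, and intervals on shares cover counting error only. Read depth per library is unknown from these lists.

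**Figure D1:**
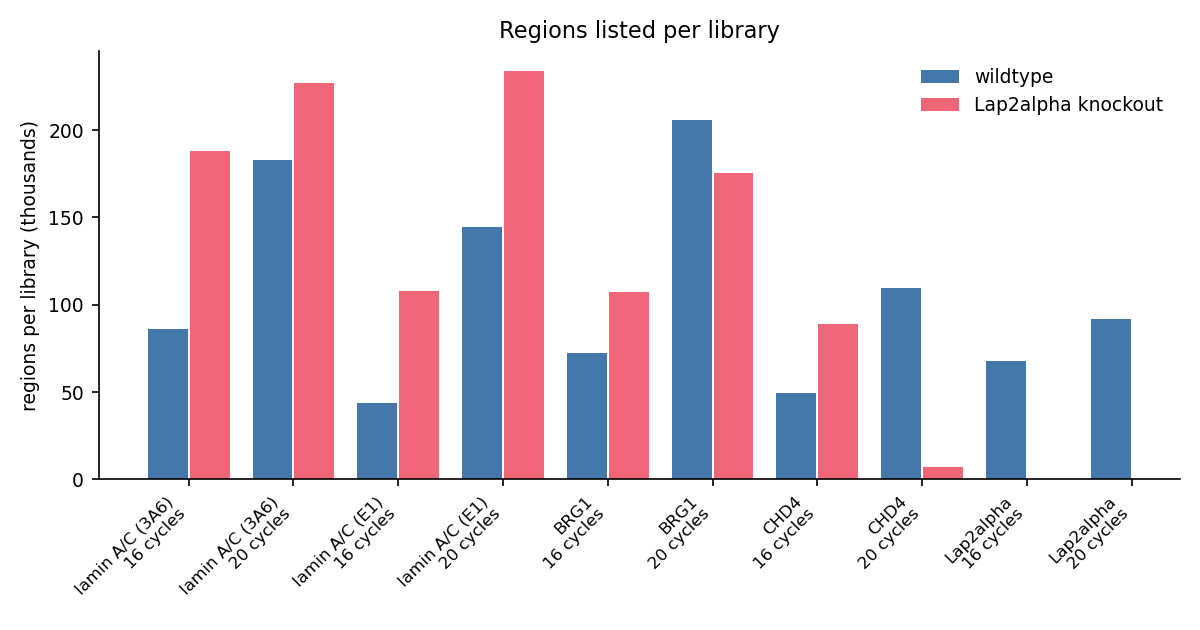
Number of regions per library (axis in units of 1000), for each antibody and sonication length, in WT (blue) and Lap2alpha KO cells (red); each bar is 1 library, and Lap2alpha was plotted for WT only. KO bars are the higher ones in all 4 lamin A/C pairs, while the KO CHD4 list at 20 cycles holds only 7283 regions.

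The genes of the proteins under study were looked at first. Tmpo, which encodes Lap2alpha together with the other LAP2 isoforms (chromosome 10), held no lamin A/C region in any WT library and 3 regions only in the KO 3A6 library at 16 cycles. BRG1 regions lay in Tmpo in all 4 BRG1 libraries, 5 and 11 in WT and 9 and 9 in KO at 16 and 20 cycles. Lmna, the lamin A/C gene (chromosome 3), held no lamin A/C region in any of the 8 lamin libraries. It was 39.0% covered by BRG1 regions in WT at 20 cycles, 32.0% and 37.0% covered in KO at 16 and 20 cycles, and uncovered in WT at 16 cycles. Chd4 held lamin A/C regions in both KO 3A6 libraries, 5 at 16 cycles and 1 at 20 cycles, and in no WT library. Peak lists of these antibodies do not show whether Tmpo was deleted, so the genotype labels were taken as given.

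The main comparison asked where lamin A/C regions lay with and without Lap2alpha. The largest excess of lamin A/C coverage in KO cells was over these 10 genes, 4 of them in 1 stretch of chromosome 6. Clec2h, a C-type lectin gene of the natural killer gene complex (chromosome 6, 128662385 to 128677374, GRCm38), was 0.74% ± 0.87 covered in WT and 12.5% ± 4.64 in KO (SD, n = 4 libraries each). Its neighbours stood with it: A2ml1 was 12.2% ± 7.62 covered in KO against 0.46% ± 0.55 in WT, Clec2m 10.1% ± 3.52 against 0, and Clec2f 9.63% ± 7.04 against 0.40% ± 0.79. Pvrig, a receptor of lymphocytes (chromosome 5), was 11.7% ± 8.32 covered in KO and not at all in WT. Coverage was likewise higher in every pair over Iapp, the islet amyloid gene, by 10.6 ± 6.46 percentage points, over the cystatin gene Cst8 by 11.7 ± 9.18, over Serpina16 by 9.97 ± 3.33, over the cytochrome P450 gene Cyp2j6 by 9.81 ± 9.27, and over the interleukin 36 gene Il1f6 by 9.67 ± 9.50.

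Lamin A/C coverage was lower in KO in every pair over a smaller set of genes. Cdh11, the cadherin of fibroblasts and bone-forming cells (chromosome 8, 102632095 to 102785493), was 17.1% ± 7.96 covered in WT and 1.77% ± 0.91 in KO. Sorcs3, a neuronal sorting receptor gene on chromosome 19, was 15.6% ± 9.33 covered in WT and 4.28% ± 3.72 in KO. Hnf4g, a nuclear receptor gene on chromosome 3, was at 11.9% ± 5.11 and 2.32% ± 1.00. The zinc finger gene Zfp982 was at 22.4% ± 8.05 and 12% ± 8.23, and 2 other genes of chromosome 4, Aadacl3 and Aadacl4fm4, differed by -9.76 ± 6.09 and -10.8 ± 10.6 percentage points. Lrrc3b, Ugt2b37, Pex5l and Spata16 completed this group with differences between -9.13 and -8.43 percentage points.

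Of 16853 protein-coding genes of at least 5 kb, 1611 had more lamin A/C coverage in KO in all 4 pairs and 98 had less. Independent pairs with the same shares would give 228 and 0.0489 genes. That figure gives every gene the same chance, although genes differ in length and 4293 held no region in any of the 8 libraries. Counts in both directions exceeded it, so the excess does not measure a genotype effect. The lists of KO cells were longer in each pair, and with equal numbers of the widest regions per pair the counts were 773 and 186. The genes with more coverage made up 22.4% of those on chromosome 18 and 15.5% of those on chromosome 6, against 4.84% on chromosome 7. Of the 98 genes with less, 21 lay on chromosome 19, 19 on chromosome 5, 12 on chromosome 4 and 11 on chromosome 3, and none lay on chromosomes 10, 11, 12, 13, 15, 16 or 18.

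At gene ends (within 1 kb of either end of a protein-coding gene), 51 genes had a lamin A/C region in all 4 KO libraries and in no WT library. The reverse held for 3, where independent lists would give 6.44 and 0.0643. Those figures also give every gene the same chance, and both counts exceeded them. The KO group included Klrk1, which encodes the natural killer receptor NKG2D, the interleukin gene Il1b, the kinase gene Dyrk4, Clec2h, Fbxw15, Lrrc6, Ces1g, Zar1l and Spink12. The WT group was the insulin gene Ins1, the RNA-editing cofactor gene A1cf and Mup-ps16. A further 35 genes had a gene-end region in all 8 libraries, and 8977 in at least 1.

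Gene groups fixed in advance were compared next. Over all protein-coding genes 2.08% to 8.96% had a lamin A/C gene-end region per WT library. None of 32 fibroblast and extracellular matrix genes, 35 cell cycle genes, 24 nuclear envelope genes, 13 NuRD genes or 25 housekeeping genes had a gene-end region in any WT lamin library. SWI/SNF, contractile and YAP target, and immediate early genes stood at 2.78%, 2.08% and 1.39%, and HOX genes and muscle, adipocyte and melanocyte genes at 0. In WT gene bodies fibroblast, cell cycle and nuclear envelope genes lay at the 1.08th, 0.17th and 3.37th percentile of matched lists, beside HOX at the 1.49th and muscle, adipocyte and melanocyte genes at the 3.57th. NuRD genes lay at the 1.5th and housekeeping genes at the 11.15th. Not all groups were low: immediate early, contractile and YAP target, and SWI/SNF genes lay at the 28.5th, 36.6th and 55.2nd. In KO the first 5 groups stood at 11.7%, 7.86%, 8.33%, 7.69% and 8% of members per library, differences at the 67.4th, 31.8th, 33.7th, 32.7th and 44.2nd percentile of 10000 random lists matched on gene length. Without the 3A6 pair at 16 cycles they stood at 9.38%, 2.86%, 2.78%, 2.56% and 5.33%, and cell cycle, nuclear envelope and NuRD genes had no gene-end region in either KO E1 library. Long neuronal genes were at 25.9% in WT and 42.0% in KO. Their gene bodies were 2.86% and 3.30% covered, the 99.9th percentile of matched lists in both genotypes. The body difference of 0.44 ± 1.36 points was positive in 2 of 4 pairs and at the 10.6th percentile. Of 28 members 10 were higher in every pair and 1 lower, against 1611 and 98 of the 16853 genes of at least 5 kb. These counts were not matched on gene length. Among the 10 Lrp1b was at 1.48% ± 1.29 and 4.34% ± 1.47, Ctnna2 at 1.23% ± 0.98 and 3.25% ± 1.67, and Cntnap2 at 0.05% ± 0.05 and 2.42% ± 1.44.

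Olfactory receptor genes, expressed in the nose, carried lamin A/C at 30.2% of 1110 gene ends in WT and 43.4% in KO. That difference of 13.2 ± 10.4 points exceeded all matched random lists, whose median was 8.15, while their gene-body coverage was higher in 2 of 4 pairs. With 3A6 the olfactory shares were 26.4% and 32.2% at 16 cycles and 47.4% and 50.8% at 20 cycles. Over all genes the 3A6 differences were larger, 4.41% and 22.1%, then 8.96% and 17.9%. The excess of olfactory receptor genes therefore came from E1 alone. Vomeronasal receptor genes were at 14.2% and 23.6% of 355, a difference at the 69.1st percentile. They were at 15.2% and 25.9% without the 3A6 pair at 16 cycles, a difference at the 98.5th percentile. Body differences of endothelial, leukocyte, and muscle, adipocyte and melanocyte genes lay at the 74.0th, 53.8th and 78.2nd percentile of matched lists, and that of keratinocyte genes at the 95.2nd. Without the 3A6 pair at 16 cycles these groups lay at the 70.4th, 25.4th, 46.8th and 98.9th. Of 11 endothelial genes 5 were higher in all 4 pairs, among them the angiopoietin receptor gene Tek (0.10% ± 0.12 to 2.45% ± 1.31) and the VEGF receptor gene Flt1 (0.18% ± 0.28 to 2.99% ± 1.68). Of 17 keratinocyte genes 3 were higher, Dsg3 by 3.63 ± 2.87 points, Grhl2 by 2.63 ± 1.98 and Dsc3 by 1.45 ± 1.66. The leukocyte gene Ptprc and the melanocyte genes Mitf, Tyr and Dct were higher by 1.05 to 2.69 points. They were 1 of 16 leukocyte genes and 3 of 18 muscle, adipocyte and melanocyte genes. Of all 16853 genes of at least 5 kb, 1611 were higher in all 4 pairs, a share not matched on gene length. Gene-body differences were small relative to matched lists for zinc finger genes (0.40 ± 0.40 points, 0.10th percentile), contractile and YAP target genes (0.10 ± 0.60, 3.33rd percentile) and SWI/SNF genes (0.16 ± 0.74, 4.33rd percentile, positive in 1 of 4 pairs). Without the 3A6 pair at 16 cycles the contractile and SWI/SNF values were -0.11 and -0.20. Smarca2, the BRM ATPase gene, was the SWI/SNF member with less coverage in KO (6.53% ± 4.82 to 2.03% ± 1.05). Immediate early, HOX and replication-dependent histone genes differed by -0.03 ± 0.27, 0.17 ± 0.30 and 0.18 ± 0.34 points.

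**Figure D2:**
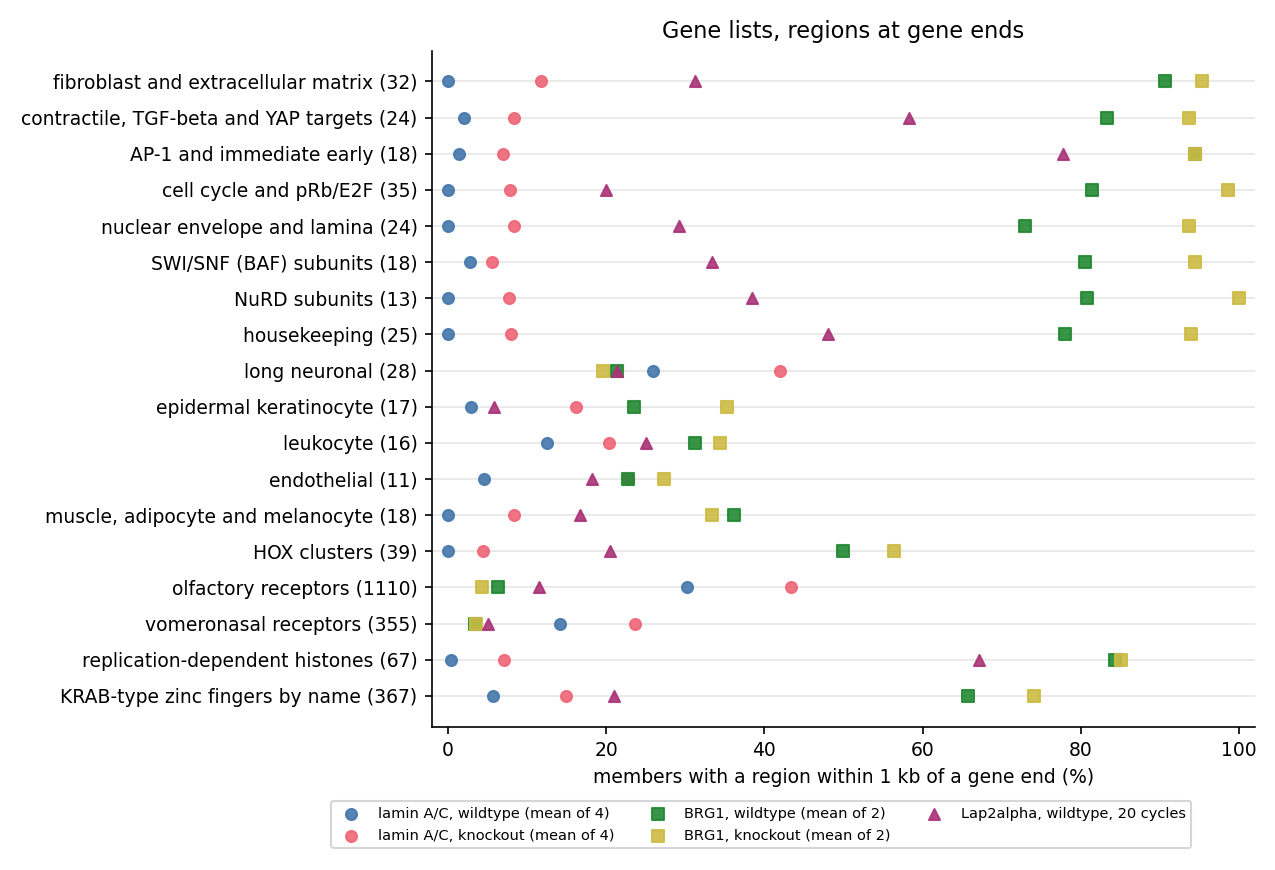
Percent of the members of each fixed gene list (number of members in parentheses) with a region within 1 kb of a gene end, as means over libraries: lamin A/C (circles, WT and KO), BRG1 (squares, WT and KO) and WT Lap2alpha at 20 cycles (triangles). Lamin A/C values are highest for olfactory receptors (30.2% in WT and 43.4% in KO) and long neuronal genes, where BRG1 values are among the lowest.

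The title of the study names open genomic regions, so the placement of lamin A/C relative to gene-rich chromosome segments was measured. A larger share of lamin A/C coverage lay in gene-rich segments in KO. The 683 bins of 1 Mb with the most protein-coding genes, which make up 25.5% of the chromosome spans, held 11.8% of the lamin A/C covered length in WT and 17.6% in KO. The difference was 5.79 ± 4.46 percentage points (SD, n = 4 pairs) and was positive in all 4 pairs. It was 12.4 points for 3A6 at 16 cycles, 4.42 for 3A6 at 20 cycles, 3.36 for E1 at 16 cycles and 2.98 for E1 at 20 cycles, and without the 3A6 pair at 16 cycles the mean was 3.58 ± 0.75. The gene-poorest bins, 23.7% of the spans, held 44.8% of the covered length in WT and 33.1% in KO, lower by a mean of -11.7 ± 4.79 points and in all 4 pairs.

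BRG1 and CHD4 libraries of the same cells differed in the same direction at 16 cycles and in the other at 20 cycles. The gene-rich share of BRG1 was 31.7% in WT and 38.7% in KO at 16 cycles, and 38.7% and 37.8% at 20 cycles. For CHD4 it was 29.6% and 43.4% at 16 cycles and 46.0% and 41.2% at 20 cycles. The WT BRG1 library at 16 cycles held 62.8% (95% Wilson interval 62.2 to 63.4) of the 25446 gene-rich sites found in the other 3 BRG1 libraries, but 82.1% (81.0 to 83.2) of 4792 gene-poor sites; in each of the other 3 libraries the gene-rich share was the higher one. At 16 cycles the lamin A/C difference in gene-rich bins therefore had the direction of the BRG1 and CHD4 differences. At 20 cycles no such shared direction was seen, though the CHD4 value there rests on a KO list of 7283 regions. For BRG1 and CHD4 the WT library at 16 cycles had the lowest share. WT lamin A/C shares were instead close at 16 and 20 cycles, 11.4% and 12.6% with 3A6 and 10.8% and 12.6% with E1.

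**Figure D3:**
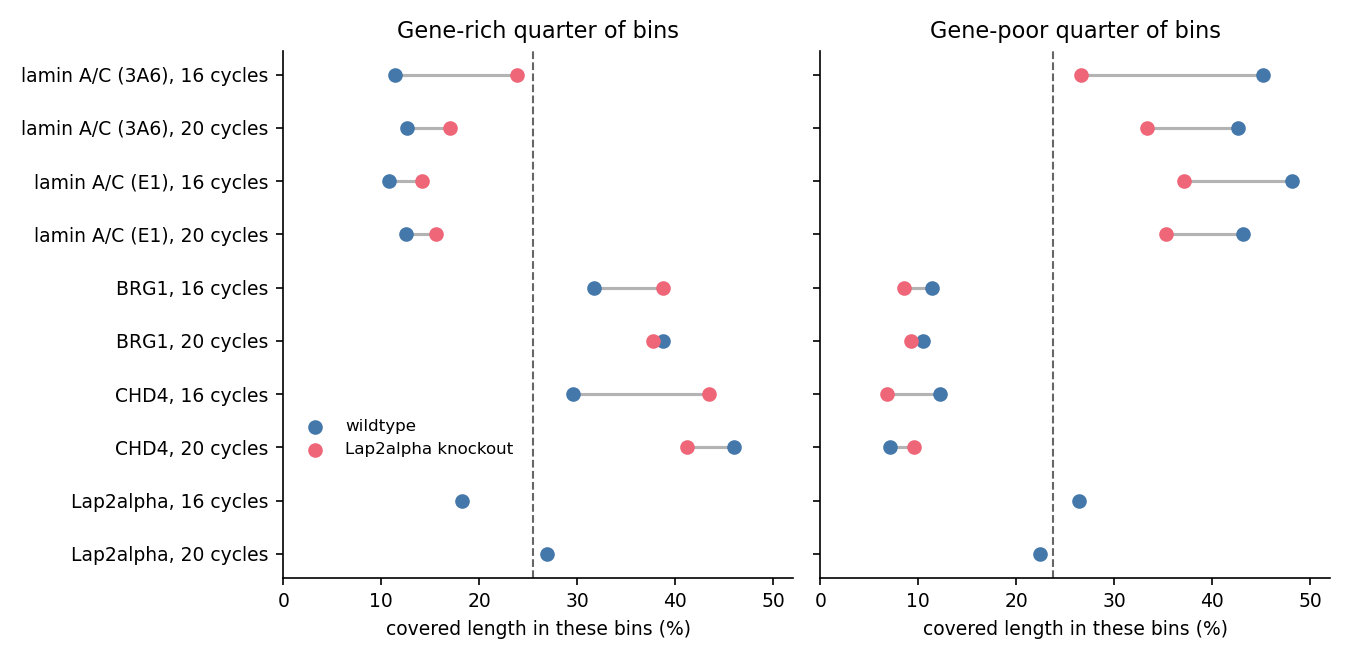
Percent of each library's covered length in the gene-richest (left) and gene-poorest (right) bins of 1 Mb, for WT (blue) and KO (red); each point is 1 library and the dashed line is the share of the chromosome spans in these bins. All 4 lamin A/C pairs shift right on the left panel and left on the right panel, while BRG1 and CHD4 shift right at 16 cycles only.

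Lamin A/C regions at gene ends made up 1.35% of regions in WT and 2.07% in KO, a difference of 0.71 ± 0.56 percentage points that was positive in all 4 pairs and 0.44 without the 3A6 pair at 16 cycles. Random intervals of 300 bp hit gene ends at 3.42%, above every lamin A/C library. The number of lamin A/C regions was higher in KO in all 4 pairs, by 0.86 ± 0.44 on the log2 scale or 1.81-fold. The covered length was higher in 3 pairs, 0.70 ± 0.60 on the log2 scale, and lower for 3A6 at 20 cycles, at 66.5 Mb in WT and 60.4 Mb in KO.

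Whether lamin A/C reached sites of the chromatin remodellers was compared next. At the 44613 BRG1 sites shared by all 4 BRG1 libraries, lamin A/C (3A6) regions were present at 1.77% (1.65 to 1.90) of sites in WT and 16.1% (15.8 to 16.4) in KO at 16 cycles, and at 1.01% and 6.90% at 20 cycles. With E1 the values were 0.946% and 4.76% at 16 cycles and 0.330% and 0.816% at 20 cycles. These are 9.11-fold, 6.86-fold, 5.04-fold and 2.48-fold differences, against 2.19-fold, 1.24-fold, 2.46-fold and 1.62-fold more regions in the same KO lists. The shared sites were chosen after seeing the data, and against the whole WT BRG1 lists the contrast was smaller in every pair. There 2035 lamin A/C regions in WT and 11394 in KO overlapped with 3A6 at 16 cycles, and 9510 and 17905 at 20 cycles. With E1 the numbers were 815 and 2877, then 2738 and 5732. CHD4 regions lay at 59.9% of the same sites in WT and 83.8% in KO at 16 cycles. At 20 cycles, with the short KO list, they lay at 78.9% and 5.94%. At 16 cycles the CHD4 difference thus had the same direction as that of lamin A/C. WT CHD4, however, was lower at 16 than at 20 cycles, while WT lamin A/C was higher at 16 cycles with both antibodies. Shares at these sites were not set against placed or shifted regions.

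Counted from the lamin A/C side, 2.83% of regions overlapped a BRG1 region of the same genotype in WT and 5.29% in KO, a difference of 2.46 ± 3.01 points, positive in 3 of 4 pairs. The pair at 3A6 and 16 cycles went from 2.37% to 9.11%, which was 0.94-fold and 2.35-fold of the overlap of randomly placed regions, and without it the mean difference was 1.04. At 3A6 and 20 cycles the overlap was 0.73-fold and 1.35-fold of the placed overlap. With E1 it stayed below the placed overlap in both genotypes, 0.74-fold and 0.81-fold at 16 cycles and 0.27-fold and 0.26-fold at 20 cycles. Against regions shifted by 10 kb, which keep the neighbourhood, the overlap was above the control in every library. It was lower in KO in all 4 pairs with the BRG1 list of each genotype, and also with the WT BRG1 list for both. With the KO BRG1 list for both it was lower in 2 pairs. With the list of each genotype, 3A6 gave 3.83-fold and 2.76-fold at 16 cycles and 3.25-fold and 3.05-fold at 20 cycles. E1 gave 3.12-fold and 2.69-fold, then 1.30-fold and 1.11-fold. In the 3 pairs with higher overlap in KO, the shifted regions overlapped BRG1 more in KO as well. Overlap with CHD4 regions was higher in KO at 16 cycles for both antibodies (by 4.39 points for 3A6 and 0.61 for E1) and lower at 20 cycles, where the KO CHD4 list was very short, so the mean of 0.43 ± 2.90 points was within the spread between pairs.

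**Figure D4:**
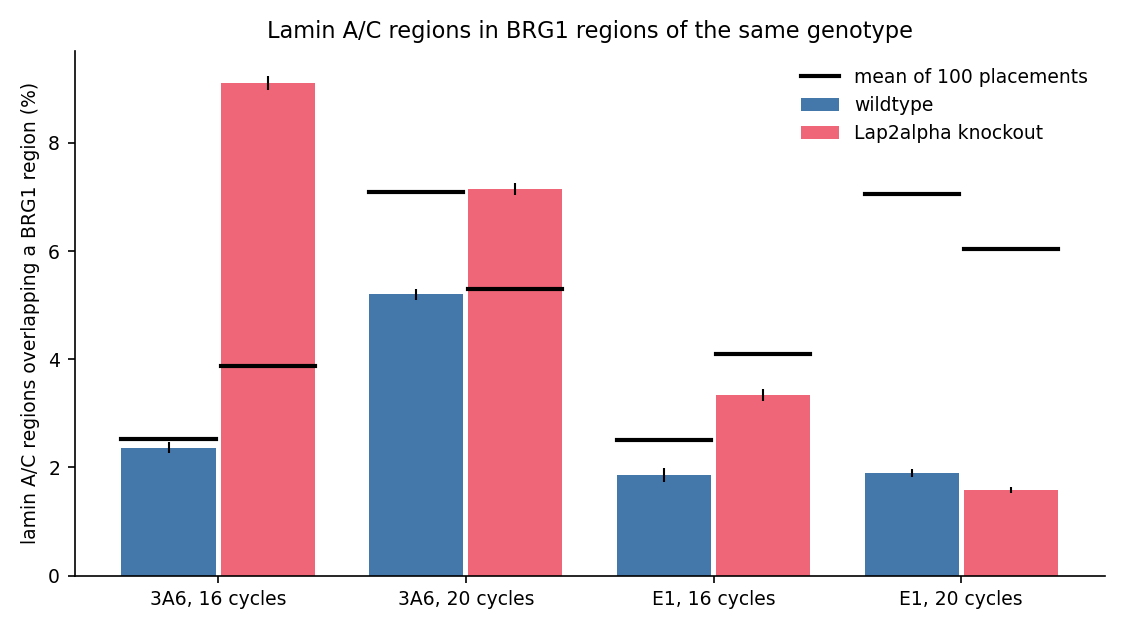
Percent of lamin A/C regions that overlap a BRG1 region of the same genotype and sonication length, for WT (blue) and KO (red); each bar is 1 library, error bars are 95% Wilson intervals (counting error only) and black lines give the mean of 100 random placements. The 3A6 libraries of KO cells, at 9.11% and 7.15%, are the ones above their placed overlap.

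How many lamin A/C regions were kept between genotypes differed by library. Of the WT regions, 17.2% and 28.6% overlapped a KO region with 3A6 at 16 and 20 cycles, and 27.2% and 51.2% with E1, all above placed regions (3.00% to 7.24%). Of WT BRG1 regions 76.2% and 40.1% overlapped a KO region, and of WT CHD4 regions 61.5% and 3.04%. Within a genotype, lamin A/C regions of 16 cycles were found again in the longer 20-cycle lists at 48.7% (3A6) and 51.7% (E1) in WT and at 19.1% and 45.7% in KO. Regions found in KO without a WT counterpart (gained) lay in gene-rich bins more than WT regions without a KO counterpart (lost). This largely restates the higher gene-rich share of the KO lists and is no separate support for it. With 3A6 the shares of covered length were 24.7% for gained and 11% for lost regions at 16 cycles, and 18% and 11.9% at 20 cycles. With E1 they were 14.3% and 9.87% at 16 cycles, and 16.1% and 10.6% at 20 cycles. Gained regions overlapped the WT BRG1 list at 6.35% and 8.59% with 3A6, against 2.32% and 4.95% of lost ones. With E1 the values were closer, 2.77% and 2.69% against 1.86% and 1.93%.

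Where Lap2alpha itself lay was measured in WT cells. The lists carry no height, so gene ends were ranked by width. Ankrd1, a YAP target and muscle-stress gene (chromosome 19, 36111965 to 36119844), was 40.4% covered on average over both sonication lengths, and Dusp1, a MAP kinase phosphatase gene, 66.1%. Jun was 62.9% covered, Plk2 28.1%, the chaperone gene Hspa5 35.2%, Anxa1 24.8% and the linker histone gene H1f4 72.7%. Vmp1, H2bc6 and Tmsb4x completed the 10 with the widest regions. Gene-end regions were present at both sonication lengths in 611 genes.

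By group, 82.1% and 67.2% of 67 replication-dependent histone genes had a Lap2alpha region at a gene end at 16 and 20 cycles, against medians of 7.46% and 11.9% in matched random lists. The AP-1 and immediate early group stood at 55.6% and 77.8% of 18 genes, the contractile and YAP target group at 25.0% and 58.3% of 24, and the fibroblast and matrix group at 28.1% and 31.3% of 32, the latter at the 91.4th percentile. Housekeeping genes stood at 16% and 48% of 25, the 93.5th and 99.9th percentile, with gene bodies at the 98.9th and 99.5th. Gene bodies of the histone, immediate early, contractile and fibroblast groups were covered above the 99.9th percentile of matched lists at both lengths. WT BRG1 coverage of these gene bodies lay at the 100th percentile in each of the groups too, so high coverage there was not particular to Lap2alpha. Vomeronasal receptor genes were low, at 3.66% and 5.07%. Of all Lap2alpha regions, 12.8% and 20.8% overlapped BRG1 and 11.8% and 13.2% CHD4, which was 3.30-fold to 7.24-fold of placed regions.

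Lap2alpha regions overlapped lamin A/C in WT above placement with both antibodies, although 11.7% of the Lap2alpha regions at 16 cycles were found again at 20 cycles. With 3A6 the overlap was 15.8% (15.5 to 16.1) at 16 cycles and 19.5% (19.2 to 19.8) at 20 cycles, 5.94-fold and 3.73-fold of placed regions. With E1 it was 4.01% and 6.63% (6.47 to 6.79), 2.51-fold and 1.60-fold. At these same sites KO cells had lamin A/C at 14.4% and 17.0% with 3A6, lower than in WT, and at 5.00% and 8.75% with E1, higher than in WT. The mean difference was -0.20 ± 2.14 points, with longer lists in KO. Relative to placed regions the overlap was lower in KO in all 4 pairs, 4.53-fold and 3.37-fold with 3A6 and 1.87-fold and 1.39-fold with E1, and with equal numbers of the widest regions the mean difference was -4.10 points. Relative to regions shifted by 10 kb the 3A6 overlaps were close in WT and KO (4.23-fold and 4.19-fold, then 3.11-fold and 3.10-fold) and the E1 overlaps lower in KO (1.73-fold and 1.55-fold, then 1.27-fold and 1.21-fold). With equal chromosome weights the mean difference was 1.72 points.

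For the remodellers, the comparison asked whether BRG1 and CHD4 sites differed without Lap2alpha. BRG1 gene-end regions appeared only in KO, at both sonication lengths, in 232 genes. The widest was at Cdh11, where gene-body coverage was 0.21% ± 0.30 in WT and 4.44% ± 0.04 in KO (SD, n = 2 libraries each). Others were Ankrd13b (3.89% ± 2.67 and 10.9% ± 0.58), Zbed3, S100a3, Fam13c, the cell cycle transcription factor gene Mybl2 (2.14% ± 0.48 and 5.72% ± 1.44), Arfgef2, Zfp821, Bmp10 and Syn3. In 82 genes they appeared only in WT. Among these were Sulf1, a heparan sulfate sulfatase gene (6.69% ± 2.94 and 0.54% ± 0.23), Bmp3, an antagonist of BMP signalling (8.18% ± 0.26 and 1.70% ± 0.70), Pi15 (9.88% ± 2.91 and 1.81% ± 2.56), Mreg, Wfdc18, Cavin4, Tmeff1, Defb33, Mgat4e and Cdh18. A BRG1 region was present in all 4 libraries at 7427 genes. Independent lists with the same chance for every gene would have given 1651 and 938 genotype-specific genes.

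BRG1 covered the genes that fibroblasts use in both genotypes. Gene ends of fibroblast and matrix genes had a BRG1 region at 90.6% in WT and 95.3% in KO, immediate early genes at 94.4% in both, and olfactory receptor genes at 6.31% and 4.32%. Fibroblast gene bodies were 13.8% covered in WT and 16.4% in KO, a difference of 2.59 ± 3.56 points at the 99.6th percentile of matched lists. It came from 16 cycles (9.49% and 14.6%), where the WT library lacks gene-rich BRG1 sites, with 18.02% and 18.10% at 20 cycles. Contractile and immediate early genes were likewise higher in KO at 16 cycles, and lower at 20 cycles (24.8% and 21.6%, 40.6% and 38.8%). The collagen gene Col1a2 was at 19.9% ± 4.32 and 31.1% ± 4.30, with nearly equal differences in both pairs (SD of 0.02 points). Col5a1, Col5a2 and Col6a2 were higher by 3.91 ± 3.48, 0.98 ± 0.90 and 2.24 ± 0.32 points, and the smooth muscle gene Tagln by 13.2 ± 5.71. Of 32 fibroblast and matrix genes 13 were higher in KO in both pairs and 3 lower, and of 24 contractile genes 8 and 3. The adipocyte gene Fabp4 was at 0.33% ± 0.46 and 12.4% ± 1.72, and the keratin genes Krt14 and Krt15 were higher by 12.9 ± 4.07 and 17.8 ± 0.78 points. Of 18 muscle, adipocyte and melanocyte genes 6 were higher in both pairs and 2 lower, and of 17 keratinocyte genes 4 and 2. The YAP target Ccn1 was lower, 68.8% ± 29.4 and 48.1% ± 20.6.

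The number of BRG1 regions was higher in KO at 16 cycles (0.57 on the log2 scale) and lower at 20 cycles (-0.23), so no common direction was found. With intervals as listed it was higher in KO in both pairs, by 0.38 ± 0.27. At 20 cycles 206126 intervals were listed in WT and 235621 in KO, so the direction there depends on merging. The share at gene ends was higher in KO at both lengths, from 11.9% to 12.5% and from 8.89% to 9.76%, by 0.76 ± 0.16 points. CHD4 regions were more numerous in KO at 16 cycles (0.84 on the log2 scale) and far fewer at 20 cycles (-3.91, 109769 against 7283 regions). The CHD4 gene-end share was 8.26% and 13.5% at 16 cycles and 14.3% and 11.3% at 20 cycles.

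With 7283 regions in the KO list at 20 cycles, CHD4 differences at single genes rest on the 16-cycle pair. CHD4 gene-end regions were present in both WT libraries and in no KO library at 240 genes, led by Fhit, Jun, Rabepk, Mplkip, Atm, Npat, Cd300c, Gprc5a, Zfp947 and Ctla4. Jun, the AP-1 transcription factor (chromosome 4, 95049036 to 95052222), was 60.8% ± 7.66 covered in WT and not covered in KO. At 16 cycles Egr1 was at 49.5% in WT and 14.0% in KO, Itgb1 at 12.9% and 4.67%, and Rbbp4, a NuRD subunit gene, at 6.36% and 3.62%. The short KO list at 20 cycles left few genes that could be higher in both pairs. Group means at 16 cycles were higher in KO. Immediate early bodies were 14.2% and 23.0% covered in WT and KO, fibroblast bodies 7.27% and 14.4%, NuRD bodies 1.99% and 4.68%, and all genes 1.08% and 3.83%. Only in KO were 16 genes, led by Aldh3a1, Frs2, Golga5, Klf13 and Mpped2. Independent lists with the same chance for every gene would give 1054 genes with CHD4 only in WT and 160 only in KO, both above the counts found.

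Longer sonication and the choice of lamin antibody were compared within genotypes. Lists at 20 cycles were longer than at 16 cycles for 8 of 9 combinations, the exception being KO CHD4, and the mean log2 ratio was 0.49 ± 1.61 over 9 and 0.98 without CHD4. The share of E1 regions that overlapped 3A6 regions was 14.4% and 28.3% in WT at 16 and 20 cycles and 6.2% and 14.8% in KO, 1.77-fold to 4.73-fold of placed regions and 1.25-fold to 1.50-fold of regions shifted by 10 kb.

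Chromosomes differed widely in lamin A/C density. In WT cells at 16 cycles E1 regions numbered 61.4 per Mb on chromosome 8 and 1.55 per Mb on chromosome 13, a 39.7-fold range, and 3A6 regions spanned a 10.3-fold range between the same chromosomes. In KO cells at 16 cycles the range was 5.17-fold with E1, and 2.81-fold with 3A6, for which chromosome 8 was the lowest. The X chromosome held 18.5% of E1, 13.3% of 3A6 and 21.3% of Lap2alpha regions in WT at 16 cycles, against 6.31% of the spans. In KO at 16 cycles it held 7.29% of E1 and 3.72% of 3A6 regions, and at 20 cycles WT and KO lamin A/C libraries lay between 5.54% and 6.94%.

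**Figure D5:**
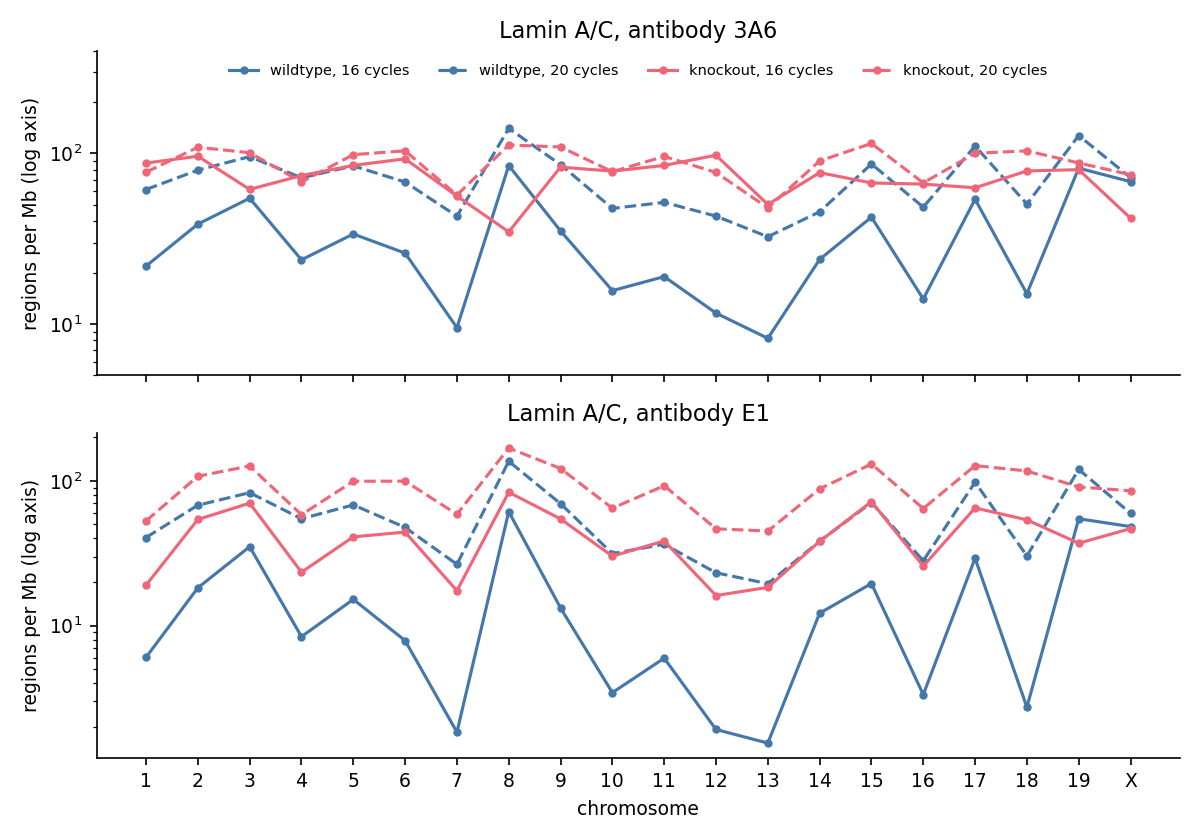
Lamin A/C regions per Mb (log axis) on each chromosome for antibodies 3A6 (top) and E1 (bottom), in WT (blue) and KO (red), at 16 cycles (solid) and 20 cycles (dashed); each line is 1 library. WT libraries at 16 cycles vary most, from 1.55 to 61.4 per Mb with E1, and the KO 3A6 library at 16 cycles is lowest on chromosome 8.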

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

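Tests written after their result was seen were those of list length, list form, the antibody-independent difference, the WT chromosome ranks and the loss of CHD4 binding; the tests of chromosome composition, of ranks over all antibodies, of gene content and of places without CHD4 were written before.

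Several KO minus WT results had opposite directions at 16 and 20 cycles, and these differences were not tested. Lamin A/C overlap with CHD4 was 2.50 points at 16 cycles and -1.64 at 20 cycles, 4.13 points apart. BRG1 region number was 0.57 and -0.23 on the log2 scale, 0.80 apart, and the CHD4 gene-end share 5.27 and -3.00 points, 8.27 apart. With intervals as listed the BRG1 number was higher in KO at both lengths, so its opposite direction appears only after merging. The gene-rich share of BRG1 was 6.99 and -0.98 points, 7.98 apart, and that of CHD4 13.9 and -4.80, 18.7 apart. Lamin A/C at Lap2alpha sites was -1.96 points with 3A6 and 1.56 with E1, a difference of -3.52 that was not tested.

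The shift of lamin A/C toward gene-rich bins in KO (5.79 points) was weighed first. Unequal chromosome composition would have to remove most of it, but it was 4.80 with equal chromosome weights. It was likewise 6.01 with equal numbers of the widest regions and 6.25 over pairs of lists of one form, positive in every pair each time. The share was higher in KO on 20 and 17 of 20 chromosomes with 3A6 and on 12 and 16 with E1 at 16 and 20 cycles. Width is not a score, and it is limited to a common maximum in several lists. The widest regions need not be the strongest, so the test of list length cannot decide whether longer lists reach weaker regions. At 16 cycles a lower yield of gene-rich fragments in WT libraries whatever the antibody remains a candidate explanation. BRG1 and CHD4 showed a mean difference of 10.4 points there, above the 7.89 of lamin A/C. WT lamin A/C shares, however, were close at 16 and 20 cycles, 11.4% and 12.6% with 3A6 and 10.8% and 12.6% with E1. KO shares at 16 and 20 cycles were 23.8% and 17.0% with 3A6, and 14.2% and 15.5% with E1. The larger 3A6 difference at 16 cycles thus went mostly with the KO library. At 20 cycles the remodellers differed by -2.89 points (BRG1 -0.98, CHD4 -4.80) while lamin A/C differed by 3.70; both remodeller pairs and the 3A6 pair join lists of different form, and the KO CHD4 list is very short, so this leaves the explanation open. That lamin A/C moves to gene-rich regions without Lap2alpha stays a hypothesis.

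The uneven spread of WT lamin A/C and Lap2alpha regions over chromosomes, with chromosome 8 the densest and chromosome 13 the sparsest for lamin A/C, was weighed next. The 3A6, E1 and Lap2alpha libraries of WT cells at 16 cycles ranked the 20 chromosomes alike, with Spearman correlations of 0.97 or more, but they were picked as alike, and WT BRG1 at 16 cycles correlated with them at 0.41 to 0.45 and spanned a 2.21-fold range, lowest on X, while WT CHD4 correlated with them at 0.78 to 0.84. Over antibodies of one genotype the lowest correlation was -0.20, between 3A6 and E1 in KO at 16 cycles; the bound set in advance was met through the KO 3A6 library alone, as KO 3A6 and E1 at 20 cycles correlated at 0.91, so chromosome copy number or another property of the cells is not decided. Gene content gave correlations between 0.041 and 0.30 over the 10 libraries. All fell short of the size set in advance for gene content as the cause, which argues against it as the main source of the spread. As all had 1 sign, the outcome set in advance against it was not met either. A shared input was not separated from copy number, as input libraries were not analysed here.

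The number of CHD4 regions in KO was 0.84 on the log2 scale relative to WT at 16 cycles and -3.91 at 20 cycles, 4.76 apart and not tested. A loss of CHD4 binding in KO cells would lower the number at both lengths, but the 0.84 at 16 cycles does not decide, since a WT list short of gene-rich sites would give it too. A list made mostly of places without CHD4 stays open, since its overlap with the KO CHD4 list at 16 cycles was 13.5-fold that of placed regions and 5.17-fold that of shifted ones, but 46.7% of its regions; the bound of 3-fold set in advance did not measure the share. A weak precipitation or shallow sequencing of that 1 library stays open as untested; no biological explanation was tested.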

How the results depend on the processing

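Added after seeing the data were the settings on list form, the 3A6 pair at 16 cycles, listed intervals, centre windows and chromosome weights. Lamin A/C region number, covered length, gene-rich share, BRG1 overlap and the 20 over 16 ratio kept their direction, and moved by no more than the SD between pairs, under all 10, 11, 12, 14 and 4 alternatives run for them; that SD is wide. The covered length was 0.16 with equal numbers of the widest regions, 0.35 at the median width or above, 0.29 at 20 cycles only and 0.38 with 3A6 only, and the region number 0.52 at the median width or above and 0.50 at 20 cycles only. The BRG1 overlap difference, 2.46 points, was 0.58 with E1 only and 0.82 at 20 cycles only, above 0 in 1 of 2 pairs each time. Genotype overlap, the Lap2alpha overlap with lamin A/C and antibody overlap, which have no direction, moved by no more than this SD under 7, 11 and 5. Genotype overlap was 31.0% in the main setting and 18.5% at the median width or above. For the results below the cause was not tested. The lamin A/C gene-end difference was 2.65 points within 5 kb of gene ends. The lamin A/C overlap with CHD4 was -1.64 at 20 cycles only, -0.16 with E1 only and -0.89 without the 3A6 pair at 16 cycles. Lamin A/C at Lap2alpha sites was -2.38 with regions at or above the median width, -4.10 with equal numbers of the widest regions, 1.56 with E1 only, 0.58 over lists of the same form, 0.19 without the 3A6 pair at 16 cycles and 1.72 with equal chromosome weights. BRG1 region number was -0.23 at 20 cycles only, and 0.38 with intervals as listed, where both pairs were higher in KO. CHD4 region number was 0.84 at 16 cycles only and over lists of the same form. The BRG1 gene-end difference was 1.25 at the median width or above, 1.92 with equal numbers, 1.52 within 5 kb, 1.66 with intervals as listed and 0.57 in 200 bp centre windows. The CHD4 gene-end difference was -0.11 at the median width or above, -5.76 with equal numbers and -3.00 at 20 cycles only. The gene-rich difference at 20 cycles only was -0.98 for BRG1 and -4.80 for CHD4. Genes with more or less lamin A/C coverage in every pair numbered 1611 and 98, 773 and 186 with equal numbers of the widest regions, and 1878 and 130 without the 3A6 pair at 16 cycles. GC content, motifs and gene strand were not used here.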

Other observations

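The joint look at Cdh11 and at histone genes was chosen only after the results were seen, and no tests were run on them.

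The cadherin gene Cdh11 was named by 2 separate rules, first among the genes with less lamin A/C coverage in KO (17.1% ± 7.96 to 1.77% ± 0.91, n = 4 libraries each) and first among the genes with a BRG1 gene-end region only in KO (0.21% ± 0.30 to 4.44% ± 0.04 of the gene body, n = 2 each). Cdh18, a neuronal cadherin gene on chromosome 15, had BRG1 gene-end regions only in WT, with body coverage of 4.53% ± 2.03 and 1.00% ± 0.14. BRG1 coverage was also higher in KO in both pairs over the immediate early gene Junb (12.4% ± 15.1 to 58.7% ± 11.4), the HOX gene Hoxb2 (40.2% ± 15.3 to 80.0% ± 5.12) and Banf1, which encodes a chromatin-binding protein of the nuclear envelope (3.86% ± 5.45 to 24.9% ± 12.4).

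Replication-dependent histone gene bodies were covered by BRG1 at 35.1% in WT and 49.2% in KO at 16 cycles, and at 41.0% and 32.1% at 20 cycles. CHD4 covered 35.6% in WT and 46.9% in KO at 16 cycles, and 49.2% and 0.0143% at 20 cycles, where the KO list is very short. Lap2alpha covered 29.3% and 18.9% at 16 and 20 cycles. Lamin A/C covered none of them in WT and 0.18% in KO, with gene-end regions at 0.37% of these genes in WT and 7.09% in KO. In WT, CHD4 covered H4c11 in full in both libraries, and in KO H4c11 was 91.5% covered at 16 cycles and not covered at 20.

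A hypothesis, not tested, is that Cdh11 loses contact with lamin A/C and becomes open to BRG1 when Lap2alpha is absent. Cdh11 lies on chromosome 8, the chromosome with the most lamin A/C regions per Mb in WT at 16 cycles and the fewest in the KO 3A6 library at 16 cycles. With E1, chromosome 8 had more regions per Mb in KO than in WT (83.5 and 61.4 at 16 cycles, 168.6 and 136.7 at 20) but a lower share of the longer KO lists (9.78% and 17.7%, 9.11% and 11.9%), so the difference of Cdh11 was not separated from that of the chromosome. Of 838 genes of at least 5 kb on chromosome 8, 55 (6.56%) had more coverage in KO in every pair and 8 (0.955%) had less. Over all 16853 genes of at least 5 kb these numbers were 1611 and 98. Few genes of chromosome 8 changed as Cdh11 did, though KO lists were longer. Its share of genes with less coverage was still above that of all genes, and its share with more was below. The counts therefore do not set Cdh11 apart from its chromosome. Whether Lap2alpha regions at histone and immediate early genes depend on the protein was not examined, as Lap2alpha ChIP in KO cells was not analysed here.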
